A study of Mus musculus with 10 samples.

How the data were processed

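Gene expression was measured on 10 microarrays of total RNA from microglia that had been sorted by flow cytometry, per the labels. Microglia are the resident macrophages of the brain. The mice were males 8 to 12 weeks old, either C57BL/6 (WT) or lacking Trem2, a lipid-sensing receptor on the surface of microglia. Cuprizone is a copper chelator that kills oligodendrocytes and strips axons of myelin. Per the labels, mice received a diet with 0.2% cuprizone for 4 or 12 weeks, separate mice then returned to normal food for 2 weeks, and controls received no cuprizone. Sorted cells went directly into lysis buffer, RNA was extracted with a spin-column micro kit, and nanogram amounts of it were amplified into biotinylated cRNA, per the labels' protocols. The markers used for the sort are not given in the sources used here.

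The deposited table holds linear intensity values, 1 per probe and array. The probe summarization, background correction and normalization behind these deposited intensity values are not given in the sources used here. Medians of the 10 columns lay between 37.6 and 39.3, column minima between 2.22 and 2.63 and column maxima between 10759.9 and 12461.6. The columns were close to a common scale as deposited. Log2 was taken first, and no further scaling was applied in the main analysis. Of the 24567 probes in the table, 21259 named 1 gene in the platform's annotation, 1274 named several and 2034 were not listed there. The single-gene probes named 19749 genes, and 21182 of these probes matched the RefSeq gene table of the mouse assembly GRCm38.p6 by Entrez identifier, which updated 0 symbols. Coordinates were not printed, because the build behind the array's annotation is not given in the sources used here. Where several probes named a gene (888 genes), the brightest was kept, and the mean over its probes was an alternative. Genes entered the tests when at least 2 arrays exceeded the table's median of 5.27 on the log2 scale, or 38.5 as linear intensity, which left 10792 genes. Levels near that median are close to background, so differences of dim genes can be compressed.

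Genotype and diet from the labels gave 6 groups. The controls had 1 library per genotype, and the cuprizone and recovery groups had 2 each, namely 1 library fed for 4 weeks and 1 fed for 12 weeks. The labels name no replicate animals or pools, so the p-values do not measure a spread between known replicates. They measure only the spread between these samples, described with each model below, which may be technical. The Trem2-/- library titled as 12 weeks on cuprizone carries a time label of 4 weeks. It was counted as 12 weeks, with 4 weeks as an alternative. The submitters' sample numbers fall into 2 runs: a first run of 6 arrays with the controls and all libraries titled 4 weeks, and a second run of 4 arrays with all libraries titled 12 weeks. Feeding time and run therefore cannot be told apart, and no control array lies in the second run. For this reason the titled duration, with the controls placed beside the 4-week libraries, was entered as a block in an alternative fit, and its values are printed beside the main ones where it changed a list's camera call or moved a comparison's count of genes by over 1.5 times.

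Gene tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 intensities, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). All adjusted p-values of single genes come from limma. A first model fitted the 6 group means, left 4 residual degrees of freedom and gave 10 contrasts. Its spread is that between the 4- and 12-week libraries of a group, so it includes differences by feeding time and run. In contrasts with a control group, the single control library was assumed to vary like the other groups. A second model compared the genotypes over the 5 diet conditions with the condition as a block, and a further model compared 12 with 4 weeks over 8 arrays with the group as a block. The spread of the second model is how the genotype difference varies over the conditions. It is therefore large for genes whose response to diet differs between genotypes. The control libraries of the 2 genotypes have no replicates, so their differences are given without a test. For them, the median of a gene list was placed among 10000 random lists of matched size and mean level.

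The 27 gene lists were Trem locus, TREM2 signalling partners, homeostatic microglia, disease-associated microglia, cholesterol synthesis, cholesterol efflux and lipid handling, lysosome, phagocytic receptors, MHC class II, MHC class I, interferon response, proliferation, cytokines and chemokines, trophic factors, immediate early, glycolysis, and, as markers of other cells, oligodendrocyte, oligodendrocyte precursor, astrocyte, neuron, endothelial, T and NK cell, B cell, neutrophil, monocyte, border macrophage and erythroid. Of their 516 entries, 466 were on the array. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Some genes stand in several lists: 12 of the 28 tested disease-associated genes, 1 of the 13 border macrophage genes and 0 of the 10 neutrophil genes were also in another list.

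The groups, the tests, the gene lists, the rule for naming genes and all alternatives except 4 were fixed before the data were examined. Under the rule, the Trem locus comes first. In each comparison it names genes past the threshold with an assigned symbol (no predicted, Riken, microRNA, small RNA or Y-linked gene) whose groups did not overlap, up to the 12 largest rises and 12 largest falls. Where fewer than 5 genes passed in a direction, the 8 with the largest moderated statistic are named as not passing. Up to 4 members of each list with the largest differences are named as well, and between the control libraries the 8 largest rises and falls. The alternatives, fixed before the files were seen, were quantile normalization, subtraction of array medians, no filter on dim genes, the mean over a gene's probes, variance moderation with trend and robust fitting, the blocks named above, the conflicting time label, and leaving out each library in turn. The alternatives added after the data were seen were the neutrophil list mean as a covariate, the duration block with the conflicting library at 4 weeks, and the genotype comparison in the control and 4-week libraries alone and in the 12-week libraries alone.

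The fits were tested on simulated data with the real gene means, independent genes and a spread drawn from the duration-blocked fit. The duration difference estimated by that fit was added equally in all groups. This setting favours the fits with the block. It cannot show how the block behaves where feeding time or run acts differently between groups. For WT cuprizone against WT control, limma recovered 2.5% of genes changed by 1 on the log2 scale, 69.9% of those changed by 2 and 91.5% of those changed by 3. For the genotype difference in that response the shares were 0%, 9.9% and 60.8%, and for Trem2-/- against WT on cuprizone they were 12%, 88.8% and 97.2%. With titled duration as a block they were 36.5%, 96.3% and 99.4% for WT cuprizone against control. The blocked shares were 8%, 84.5% and 97.7% for the genotype difference and 73.6%, 99.7% and 100% for the genotypes on cuprizone. Mean false calls were 0.2, 0 and 0.2 without the block and 6.8, 6 and 9.2 with it, in that order. In all comparisons the small number of arrays limits the precision. The 2034 unlisted probes and the 1274 probes naming several genes entered no gene comparison and are given by identifier only.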

Results

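Expression was profiled in microglia sorted from WT and Trem2-/- mice to ask how Trem2 shapes the response of microglia to loss of myelin and to recovery from it. Each genotype gave 5 libraries: a control, 4 and 12 weeks on cuprizone, and the same feeding times followed by 2 weeks on normal food. Cuprizone and recovery groups thus held 2 libraries each and control groups 1. The arrays were alike in brightness, with median intensities of 37.6 to 39.3. Correlations of log2 intensity across all probes in the table were 0.983 to 0.991 between arrays of the same run of sample numbers (21 pairs) and 0.974 to 0.983 across the runs (24 pairs). The first principal component, with 43.9% of the variance, placed the 6 libraries of the first run between -17.92 and -9.63 and the 4 libraries of the second run, all titled 12 weeks, between 16.37 and 27.85. Values below are log2 differences ± SE from limma unless named as levels.

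Trem2 itself matched the genotype label in every library. Its log2 intensity was 10.66 to 10.81 in the 5 WT libraries and 7.26 to 7.85 in the 5 Trem2-/- libraries, a difference of -3.13 ± 0.10 (adjusted p = 4.3e-07, lower in 5 of 5 diet conditions). The remaining signal lay above the table's median of 5.27. Which part of the gene was deleted, and whether the probes lie inside it, is not given in the sources used here. Trem2 did not differ between diets in WT cells (0.04 ± 0.29 for cuprizone against control, adjusted p = 0.999). Of its neighbours in the Trem cluster, Treml1 and Treml2 were measured above the filter, with genotype differences of 0.18 ± 0.11 and -0.46 ± 0.26 that did not pass.

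**Figure D1:**
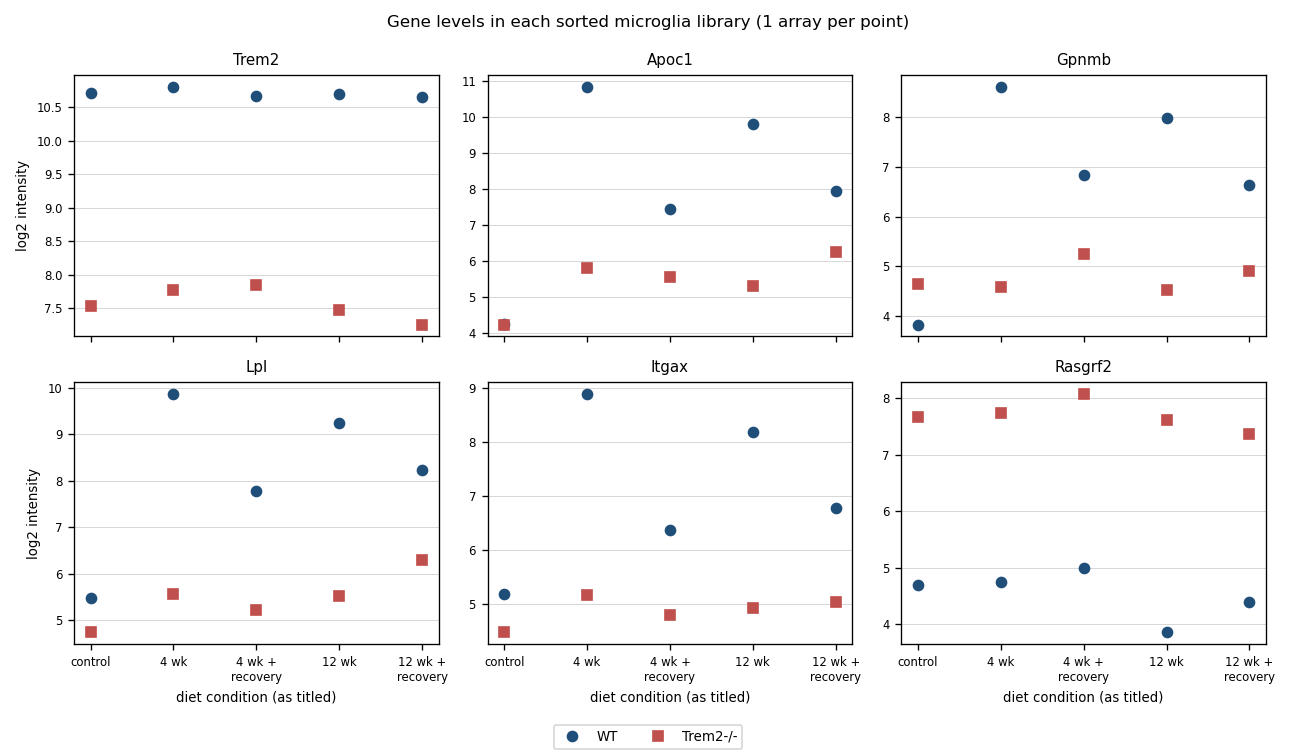
Log2 intensity of 6 genes (vertical axes) in each of the 10 libraries, arranged by diet as titled (horizontal axes), 1 array per point, WT as blue circles and Trem2-/- as red squares. Apoc1 reached 10.83 and 9.79 in the WT libraries on cuprizone against 4.26 in the WT control, and 5.80 and 5.31 in the Trem2-/- libraries on cuprizone, while Rasgrf2 lay between 7.36 and 8.07 in all Trem2-/- libraries and between 3.86 and 4.99 in all WT libraries.

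In WT microglia, 16 genes were higher in the 2 libraries on cuprizone than in the 1 control library, 8 of them members of the disease-associated microglia list. The spread of the control itself was not measured. Apoc1, an apolipoprotein, rose by 6.05 ± 0.48 on the log2 scale (adjusted p = 0.0059), from a level of 4.26 in the control library to 10.31 ± 0.73 (SD, n = 2). Gpnmb, a glycoprotein of phagocytes laden with lipid, rose by 4.48 ± 0.30 (adjusted p = 0.0035) and Lpl, the lipase that releases fatty acids from lipoproteins, by 4.06 ± 0.44 (adjusted p = 0.025). The elastase gene Mmp12 rose by 3.93 ± 0.51, the oxidised lipoprotein receptor Olr1 by 3.63 ± 0.44, the integrin Itgax by 3.34 ± 0.33, the receptor for apoptotic cells Axl by 3.22 ± 0.30 and the β-glucan receptor Clec7a by 3.17 ± 0.38 (adjusted p from 0.015 to 0.036). Further rises were measured for the fatty acid carrier Fabp5 (2.76 ± 0.32), the kinase Fam20c (2.59 ± 0.27), the endosomal GTPase Rab7b (2.52 ± 0.30), galectin-3 (Lgals3, 2.51 ± 0.32), Apoe (2.34 ± 0.29) and Ms4a7 (2.17 ± 0.30). Each of these genes was higher than the control in both WT libraries on cuprizone. The control levels of Apoc1, Gpnmb, Olr1 and Itgax (5.20) lay below the table's median of 5.27, near background, which leaves the size of these rises uncertain.

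Of 10792 genes tested with limma, 16 were higher and 0 lower, with 471 at an unadjusted p under 0.05. With titled duration as a block, 102 were higher and 3 lower, and 37 were higher and 0 lower with the library of conflicting labels counted as 4 weeks. Among genes with lower values, Bank1 (-1.63 ± 0.33, adjusted p = 0.23), Nav3 (-1.36 ± 0.28, adjusted p = 0.23) and Upk1b (-1.08 ± 0.23, adjusted p = 0.26) did not pass. With the block, the adjusted p was 0.026 for Nav3, 0.042 for Upk1b and 0.051 for Bank1. The count rested on few arrays: it was 2 without the 4-week WT library on cuprizone, 5 without the 12-week one or without either Trem2-/- library on cuprizone, and 11 without either Trem2-/- recovery library. Only Apoc1 and Gpnmb among the genes named above kept their call in all 9 such fits.

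The disease-associated microglia list, genes known to rise in microglia around plaques and damaged myelin, rose as a group. Of its 28 tested members, 27 had higher values, 8 passed over all genes and 18 passed when adjusted over the list alone, with a median of 1.72 (camera adjusted p = 1.9e-37). The adjusted p was 0.101 with an estimated correlation. The list median rose within the first run too, by 1.94 at 4 weeks, while the 12-week library of the second run differed from the control by 1.52. Cholesterol efflux and lipid handling genes also rose (19 of 24 higher, 4 called, 8 up and 1 down when adjusted over the list alone, median 0.38, camera adjusted p = 1.2e-09, adjusted p = 0.16 with an estimated correlation). Cytokines and chemokines had a median of 0.89, with 22 of 23 higher, 0 called and 5 adjusted over the list alone (camera adjusted p = 2.9e-11, adjusted p = 0.101 with an estimated correlation). Examples were Cxcl14 at 2.07 ± 0.46 and Cxcl2 at 2.02 ± 0.43, neither of which passed. The interferon response list had 19 of 23 members higher and a median of 0.93, with 0 called and 0 when adjusted over the list alone, 14 when adjusted over the list alone with the duration block, and values of 1.93 ± 0.92 for Ifit1 and 2.09 ± 1.28 for Cxcl10 (camera adjusted p = 3.7e-09, adjusted p = 0.101 with an estimated correlation). Trophic factors (median 0.64, 10 of 11 higher, 5 adjusted over the list alone), glycolysis (0.47, 12 of 15) and proliferation (0.34, 13 of 14, 2 adjusted over the list alone) had camera adjusted p-values of 4.3e-06, 0.00053 and 5.8e-05. For each of these 3 lists the adjusted p was 0.101 with an estimated correlation. The median of trophic factors was 0.40 with the duration block. Igf1, a growth factor for oligodendrocytes, measured 3.25 ± 0.47 (adjusted p = 0.057) and passed with the duration block at 3.41.

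Homeostatic microglia genes, which mark resting microglia, fell as a group: 28 of 29 had lower values, with a median of -0.44, though 0 passed singly and 0 when adjusted over the list alone (camera adjusted p = 2.8e-09, adjusted p = 0.299 with an estimated correlation). The median was -0.27 in the 4-week library, of the same run as the control, -0.54 in the 12-week library and -0.25 with the duration block. Examples were the hexose transporter Slc2a5 at -0.98 ± 0.34 and the lectin Siglech at -0.69 ± 0.37. Astrocyte markers also fell in camera's test (0 of 7 higher, median -0.71, adjusted p = 0.00017, adjusted p = 0.15 with an estimated correlation), with Aldoc at -1.31 ± 0.77. Other list calls were lost without 1 library. Border macrophage genes had a median of 0.53 (12 of 13 higher, 1 called and 1 adjusted over the list alone, camera adjusted p = 0.011) that became -0.07 without the 4-week library and 1.18 without the 12-week one. With the duration block the median was 1.01, with 4 called, 11 adjusted over the list alone and a camera adjusted p of 7.1e-16 (adjusted p = 0.0943 with an estimated correlation). Phagocytic receptors (0.30, 2 called, 2 adjusted over the list alone, camera adjusted p = 0.011) and lysosome genes (0.15, 0 called, 1 adjusted over the list alone, camera adjusted p = 0.024) had adjusted p-values of 0.187 and 0.297 without the 4-week library, and the lysosome median was 0.27 with the block. Neutrophil genes had a median of -1.58 (camera adjusted p = 0.015) that was -0.17 without the 12-week library. With the duration block it was -0.08 and the call was lost. With an estimated correlation these 4 lists had adjusted p-values of 0.552, 0.5, 0.552 and 0.552 in the order given.

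The other lists did not pass in this comparison. Their medians and camera adjusted p-values were 0.21 (adjusted p = 0.0814) for cholesterol synthesis, 0.10 (adjusted p = 0.399) for MHC class II, 0.16 (adjusted p = 0.133) for MHC class I and -0.12 (adjusted p = 0.119) for immediate early genes. TREM2 signalling partners stood at -0.14 (adjusted p = 0.654) and the Trem locus at 0.04 (adjusted p = 0.792). Markers of other cells gave 0.01 (adjusted p = 0.85) for oligodendrocyte, 0.22 (adjusted p = 0.328) for oligodendrocyte precursor, -0.38 (adjusted p = 0.197) for neuron, 0.27 (adjusted p = 0.0814) for endothelial, -0.24 (adjusted p = 0.369) for T and NK cell and -0.26 (adjusted p = 0.742) for monocyte genes. The duration block turned the monocyte median to 0.58, with 2 called up, 4 adjusted over the list alone and a camera adjusted p of 0.0036 (adjusted p = 0.182 with an estimated correlation). Immediate early genes passed camera with the block too, at -0.09 (adjusted p = 0.026, adjusted p = 0.556 with an estimated correlation). Of the B cell list only 2 genes were bright enough to test (median 0.29, no list test), and of the erythroid list 0. Over all comparisons of groups, camera passed 109 list tests and did not pass 191. With an estimated correlation 0 passed, and the smallest adjusted p was 0.0988, or 0.0932 with the duration block.

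In Trem2-/- microglia the same diet gave smaller values at the genes named as higher in WT cells, and no gene passed the test. The chemokine Ccl7, which attracts monocytes, measured 2.00 ± 0.25 (adjusted p = 0.4) with 10.56 and 10.36 in the libraries on cuprizone against 8.46 in the control. Its relative Ccl8 measured 1.99 ± 0.47, the interferon-inducible gene Ifi207 1.94 ± 0.28, Ms4a7 1.36 ± 0.30 and Apoe 1.11 ± 0.29. The dendritic cell chemokine Ccl17 measured -1.19 ± 0.35. The single Trem2-/- control itself differed from the WT control by -1.23 at Ccl8, -0.87 at Ifi207, -0.63 at Ccl7, -0.26 at Apoe and 0.5 at Ccl17. How much of these values stems from that 1 array cannot be told. limma called 0 genes, with 100 at an unadjusted p under 0.05 and a smallest adjusted p of 0.399. With titled duration as a block it called 13, all higher, among them Ccl7 (adjusted p = 0.0081), Ifi207 (adjusted p = 0.035) and the border macrophage genes Cbr2 (1.76), F13a1 (1.91) and Cd209f (2.10). With the library of conflicting labels, which belongs to this group, counted as 4 weeks in the block, 0 were called.

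The disease-associated list had a median of 0.06 in these cells, with 16 of 28 members higher, 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0601). With the duration block it passed camera at 0.14, with 0 called and 1 adjusted over the list alone (adjusted p = 0.0014, adjusted p = 0.56 with an estimated correlation). Other lists that passed camera only with the block were phagocytic receptors (0.08, adjusted p = 0.0715, against 0.24, 2 called, adjusted p = 5.1e-05), cholesterol efflux and lipid handling (0.10, adjusted p = 0.208, against 0.17, 1 called, adjusted p = 0.0029), interferon response (0.16, adjusted p = 0.191, against 0.22, adjusted p = 0.025), monocyte (-0.27, adjusted p = 0.515, against 0.24, 1 called, adjusted p = 0.031) and immediate early genes (-0.02, adjusted p = 0.208, against -0.09, adjusted p = 0.023). Their blocked adjusted p-values with an estimated correlation were 0.194, 0.457, 0.633, 0.457 and 0.633. Homeostatic genes had -0.07 (adjusted p = 0.208). Cytokines and chemokines rose (22 of 23 higher, median 0.41, 0 called, 2 adjusted over the list alone, camera adjusted p = 1.2e-10, adjusted p = 0.186 with an estimated correlation), at 0.23 with the block. Border macrophage genes, which mark the macrophages of the meninges and vessels rather than microglia, had 12 of 13 higher and a median of 1.16, with 0 called and 1 adjusted over the list alone (camera adjusted p = 6.6e-08, adjusted p = 0.686 with an estimated correlation). Without the 4-week library this list's adjusted p was 0.0541 at a median of 0.63. With the duration block the median was 1.67 and 7 members passed, since the list stood at 7.69 in the 4-week library and at 6.96 in the 12-week one, against 6.19 in the control. Neuron (-0.64, camera adjusted p = 0.00045) and astrocyte (-0.54, camera adjusted p = 0.00046) markers were lower than in the control, with adjusted p-values of 0.186 and 0.371 with an estimated correlation, and astrocyte markers had -0.31 with the block. The neuron median was 6.10 in the Trem2-/- control against 5.12 to 5.67 in all other libraries, so this control stands apart. Its border macrophage median of 6.19 lay below the 6.76 of the WT control, with differences of -0.81 at Cbr2, -0.7 at F13a1 and -0.78 at Cd209f. Neutrophil genes had a median of -1.58 (camera adjusted p = 0.013, adjusted p = 0.822 with an estimated correlation) that was -0.29 without the 12-week library. With the block it was 0.01 and the call was lost (camera adjusted p = 0.854).

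The response to cuprizone differed between the genotypes at Gpnmb, by -4.57 ± 0.43 (adjusted p = 0.045), 1 gene in all with 159 at an unadjusted p under 0.05. Gpnmb measured 8.62 and 7.99 in the WT libraries on cuprizone against 3.82 in the WT control, and 4.57 and 4.52 in the Trem2-/- libraries against 4.64 in their control. Both controls and the Trem2-/- libraries lay below the table's median of 5.27, near background, and 0.81 of the difference in response is the difference between the single control arrays, so its size is uncertain. This call held in 1 of 8 fits with a library left out: the count was 0 without the 4-week WT, either Trem2-/- cuprizone or any of the 4 recovery libraries. It was also 0 after subtraction of array medians. Apoc1 (-4.74 ± 0.68, adjusted p = 0.41), Mmp12 (-4.16 ± 0.72, adjusted p = 0.49) and Axl (-2.86 ± 0.43, adjusted p = 0.41) did not pass. With the duration block 9 genes passed, all lower, with adjusted p = 0.00063 for Gpnmb, 0.04 for Apoc1, 0.027 for Mmp12 and 0.043 for Axl. With the library of conflicting labels counted as 4 weeks, the block left 1 call.

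The disease-associated list responded less as a group in Trem2-/- cells, with 27 of 28 negative values, a median difference of -1.53, 1 called and 15 adjusted over the list alone (camera adjusted p = 1.2e-39, adjusted p = 0.108 with an estimated correlation). Lower responses were also found for cholesterol efflux and lipid handling (-0.34, 0 called, 5 adjusted over the list alone, camera adjusted p = 7.4e-09), interferon response (-0.56, adjusted p = 6.4e-06), glycolysis (-0.59, adjusted p = 3.4e-05) and proliferation (-0.31, adjusted p = 0.0002). With an estimated correlation the adjusted p was 0.108 for glycolysis and 0.201 for the other 3 of these lists. Trophic factors (-0.18, adjusted p = 0.0019, adjusted p = 0.201 with an estimated correlation) and endothelial markers (-0.27, 3 of 5 lower, 0 called, 1 adjusted over the list alone, adjusted p = 0.0351, adjusted p = 0.236 with an estimated correlation) responded less too. The endothelial call was lost without the 4-week Trem2-/- (adjusted p = 0.211) or 12-week WT library on cuprizone (0.0838) or either WT recovery library (0.0524). Cholesterol synthesis (-0.24) and lysosome genes (-0.16) passed at adjusted p = 0.0351 each, with 0.201 and 0.732 with an estimated correlation. These calls were lost, for synthesis, without the 4-week Trem2-/- (0.161) or 12-week WT library on cuprizone (0.207) and, for lysosome, without the 4-week WT (0.287) or 12-week Trem2-/- one (0.419). Homeostatic genes went the other way (28 of 29 higher, median 0.26, 0 called, camera adjusted p = 6.4e-06, adjusted p = 0.441 with an estimated correlation). Border macrophage (0.43, adjusted p = 0.257) and cytokine genes (-0.26, adjusted p = 0.195) passed camera only with the duration block, at adjusted p = 0.0019 and 0.03, and each had an adjusted p of 0.276 with an estimated correlation.

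Compared directly on cuprizone, Trem2-/- microglia were lower than WT at 35 genes. Apoc1 differed by -4.75 ± 0.39 (adjusted p = 0.0032), at 5.55 ± 0.35 against 10.31 ± 0.73 (SD, n = 2 each). Lpl differed by -4.00 ± 0.36 (adjusted p = 0.0049), Mmp12 by -3.96 ± 0.41, Gpnmb by -3.76 ± 0.25 (adjusted p = 0.0027), Olr1 by -3.71 ± 0.36, Itgax by -3.48 ± 0.27 (adjusted p = 0.0027), Clec7a by -3.34 ± 0.31 and Axl by -3.19 ± 0.25. The cystatin Cst7 (-3.24 ± 0.42), the growth factor Igf1 (-2.99 ± 0.38) and the proton pump subunit Atp6v0d2 (-2.95 ± 0.41) were lower as well. Rasgrf2, an exchange factor for Ras, was the 1 gene higher in Trem2-/- cells (3.38 ± 0.36, adjusted p = 0.0074). Each of these genes kept the same sign in the 4-week and in the 12-week pair. The naming rule fixed this for the falls, which it took only from genes whose groups did not overlap, so it is no separate support. Levels near background in 1 genotype leave the size of these differences uncertain. Examples are Gpnmb in Trem2-/- cells, Olr1 in Trem2-/- cells (levels of 3.64 and 4.02 in the 2 libraries) and Rasgrf2 in WT cells.

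In total limma called 1 gene higher and 35 lower, and 15 higher and 138 lower with the duration block. Without the block 482 genes had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. Leaving out a library gave 0 calls without the 12-week Trem2-/- library on cuprizone (333 at an unadjusted p under 0.05), which carries the conflicting time label. Other omissions gave 11 without the 4-week WT library, 16 without the 4-week Trem2-/- library and 17 without the 12-week WT library. The largest adjusted p in any of these fits was 0.073 for Apoc1, Lpl, Gpnmb, Itgax, Clec7a, Axl and Trem2. With that library counted as 4 weeks in the duration block, 55 genes were called.

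All 28 disease-associated genes were lower in Trem2-/- cells on cuprizone, with a median of -1.90, 13 called and 19 adjusted over the list alone (camera adjusted p = 4.2e-49, adjusted p = 0.0988 with an estimated correlation). The median was -1.66 in the 4-week pair, -1.81 in the 12-week pair and -0.13 in the control pair. Cholesterol efflux and lipid handling genes were lower (19 of 24, median -0.26, 4 called, 8 adjusted over the list alone, camera adjusted p = 8.7e-10), as were trophic factors (8 of 11, -0.26, 3 called, 3 adjusted over the list alone, adjusted p = 2.6e-05), with Csf1 at -1.99 ± 0.28, Vegfa at -1.56 ± 0.23 and Igf1 passing singly. Lists without a called gene were also lower: interferon response (21 of 23, -0.66, adjusted p = 1.1e-07), cytokines and chemokines (20 of 23, -0.57, 2 adjusted over the list alone, adjusted p = 2.5e-06), MHC class II (9 of 10, -0.40, 1 adjusted over the list alone, adjusted p = 8.5e-05) and glycolysis (12 of 15, -0.44, adjusted p = 4.3e-05). Among their members, Ifit1 measured -1.25 ± 0.75, Cxcl14 -2.22 ± 0.37 (adjusted p = 0.068), the invariant chain Cd74 -1.24 ± 0.23 (adjusted p = 0.11) and the glucose transporter Slc2a1 -0.99 ± 0.42. With an estimated correlation the adjusted p was 0.13 for cholesterol efflux, 0.126 for trophic factors, interferon response and cytokines, and 0.0988 for MHC class II and glycolysis. With the duration block 5 cytokine genes passed, among them Cxcl14 and Il12b.

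Homeostatic genes were higher in Trem2-/- cells on cuprizone (27 of 29, median 0.25, 0 called, 0 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.41 with an estimated correlation), with P2ry12 at 0.42 ± 0.18 and Slc2a5 at 0.54 ± 0.27. Lysosome genes had a median of -0.19 (24 of 29 lower, 1 called, 1 adjusted over the list alone, camera adjusted p = 0.0011), but the adjusted p was 0.0957 without the 4-week WT library and 0.142 without the 12-week Trem2-/- library. The camera calls of cholesterol synthesis (-0.10, adjusted p = 0.014), MHC class I (-0.08, adjusted p = 0.019) and proliferation (-0.15, adjusted p = 0.024) were likewise lost without 1 library. Their adjusted p-values were 0.198, 0.152 and 0.114 without a WT library on cuprizone (the 12-week, 4-week and 12-week one) and 0.162, 0.136 and 0.13 without a Trem2-/- one (the 4-week, 12-week and 12-week one), and 0.0628 for proliferation without the 4-week WT one. For these 4 lists the adjusted p was 0.521, 0.13, 0.13 and 0.221 with an estimated correlation. Phagocytic receptors (-0.01, adjusted p = 0.0788), TREM2 signalling partners (0.09, adjusted p = 0.509) and immediate early genes (0.04, adjusted p = 0.295) did not pass. Markers of other cells did not pass either: neutrophil -0.08 (adjusted p = 0.888), monocyte -0.48 (adjusted p = 0.0874), border macrophage -0.03 (adjusted p = 0.571), astrocyte 0.21 (adjusted p = 0.3), oligodendrocyte -0.11 (adjusted p = 0.491). With the duration block monocyte genes passed camera (1 called, 3 adjusted over the list alone, adjusted p = 0.0486, adjusted p = 0.302 with an estimated correlation).

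**Figure D2:**
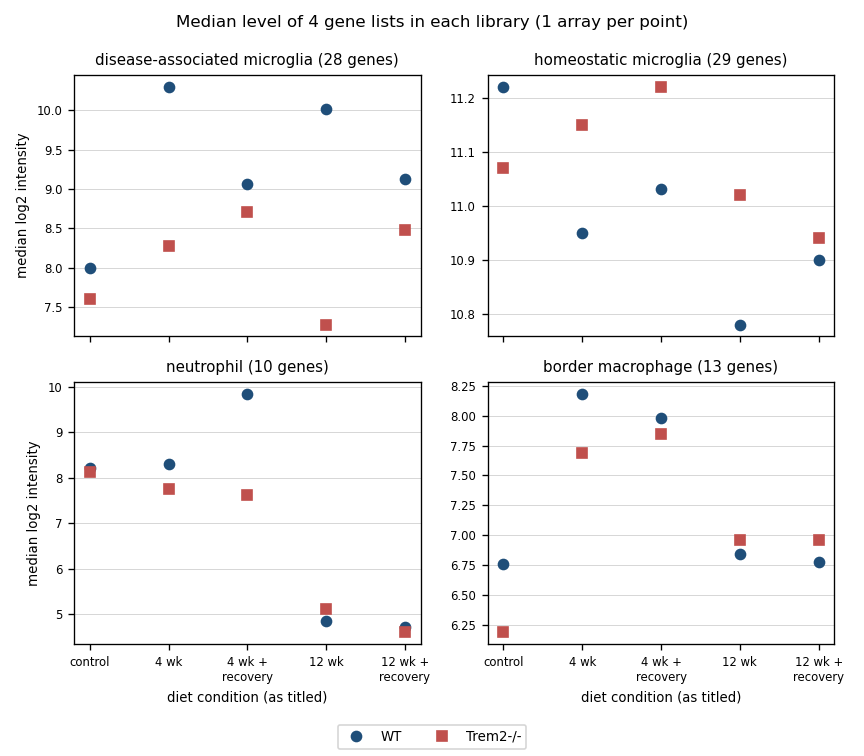
Median log2 intensity (vertical axes) over the tested members of 4 gene lists in each of the 10 libraries, arranged by diet as titled (horizontal axes), 1 array per point, WT as blue circles and Trem2-/- as red squares. The disease-associated median was 10.30 and 10.02 in the WT libraries on cuprizone against 8.28 and 7.28 in the Trem2-/- ones, and the neutrophil median was 7.63 to 9.84 in the control and 4-week libraries against 4.60 to 5.11 in the libraries titled 12 weeks.

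After 2 weeks of recovery, Trem2-/- microglia differed from WT at 3 genes, all lower. These were Trem2 (-3.12 ± 0.23, adjusted p = 0.008), the microtubule-associated ubiquitin ligase Mid1 (-3.43 ± 0.34, adjusted p = 0.022) and G530011O06Rik (-6.33 ± 0.52, adjusted p = 0.0084). The last is a Riken gene outside the naming rule, chosen after its values were seen. Rasgrf2 measured 3.03 ± 0.36 (adjusted p = 0.064) and passed with the duration block (adjusted p = 0.00015). Lpl (-2.24 ± 0.36), Olr1 (-2.19 ± 0.36) and Gpnmb (-1.67 ± 0.25) did not pass, and with the block their adjusted p-values were 0.048, 0.0025 and 0.0065. limma found 207 genes at an unadjusted p under 0.05, and 10 calls with the block, or 8 with the library of conflicting labels counted as 4 weeks. The count was 0 without either WT recovery library (473 and 129 at an unadjusted p under 0.05) or without the 12-week Trem2-/- recovery library (131).

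Disease-associated genes stayed lower in Trem2-/- cells in recovery (25 of 28, median -0.52, 0 called, 11 adjusted over the list alone, camera adjusted p = 1.2e-18, adjusted p = 0.305 with an estimated correlation). The median was -0.39 in the 4-week pair and -0.56 in the 12-week pair. The homeostatic list had a median of 0.07 (adjusted p = 0.125). Glycolysis passed at -0.15 (camera adjusted p = 0.0074, adjusted p = 0.305 with an estimated correlation) and had adjusted p-values of 0.0853 without the 4-week Trem2-/- recovery library and 0.0912 without the 12-week WT one. In the Trem locus list the median of 3 genes (0.02) and the test (lower, adjusted p = 0.014) differed in sign, since Trem2 alone fell (adjusted p = 0.305 with an estimated correlation). That call was lost without the 4-week WT (adjusted p = 0.118) or the 4-week Trem2-/- recovery library (0.0729). All 10 neutrophil genes were lower, with a median of -0.69 that did not pass (adjusted p = 0.171) but passed camera with the duration block (0 called, 3 adjusted over the list alone, adjusted p = 4.8e-05, adjusted p = 0.478 with an estimated correlation). The neutrophil median was -1.40 in the 4-week pair and -0.04 in the 12-week pair, and the 4-week WT recovery library held the highest neutrophil median of all libraries. Cholesterol efflux and lipid handling genes passed camera at -0.02 (0 called, 3 adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.689 with an estimated correlation), but not without the 4-week WT (adjusted p = 0.119) or the 12-week Trem2-/- recovery library (0.663).

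Removing cuprizone for 2 weeks gave WT microglia lower values at the genes named as higher on cuprizone, with no gene past the threshold. Apoc1 measured -2.63 ± 0.39 (adjusted p = 0.47), from 10.31 ± 0.73 to 7.43 and 7.94 in the recovery libraries. Itgax measured -1.95 ± 0.27 (adjusted p = 0.44), Gpnmb -1.56 ± 0.25 and Mamdc2 -1.56 ± 0.21 (adjusted p = 0.44). limma called 0 genes, with 295 at an unadjusted p under 0.05 and a smallest adjusted p of 0.443. The duration block gave 7 calls, all lower, among them Apoc1 (adjusted p = 0.048), Itgax and Cst7 (0.038 each) and Gpnmb and Mamdc2 (0.034 each). With the library of conflicting labels counted as 4 weeks, the block called 0.

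The disease-associated list fell as a group from cuprizone to recovery in WT cells (27 of 28 lower, median -0.86, 0 called, 16 adjusted over the list alone, camera adjusted p = 2.9e-24, adjusted p = 0.213 with an estimated correlation). Interferon response (-0.48, adjusted p = 6.6e-07), cholesterol efflux and lipid handling (-0.23, 4 adjusted over the list alone, adjusted p = 4.5e-07) and proliferation genes (-0.24, adjusted p = 0.00065) fell too, with adjusted p-values of 0.213, 0.275 and 0.213 with an estimated correlation. Homeostatic genes had a median of 0.14 (27 of 29 higher, camera adjusted p = 0.00065, adjusted p = 0.551 with an estimated correlation), but -0.01 without the 4-week recovery library, where the adjusted p was 0.545. Without the 12-week library on cuprizone it was 0.143. MHC class II (-0.38, adjusted p = 0.0018), trophic factors (-0.16, adjusted p = 0.0013), cytokines and chemokines (-0.22, adjusted p = 0.0087), lysosome (-0.11, adjusted p = 0.038) and immediate early genes (0.14, adjusted p = 0.0018) passed as well. Their adjusted p-values were 0.213, 0.213, 0.384, 0.602 and 0.384 with an estimated correlation. Each of these 5 calls was lost without 1 library. MHC class II was lost without the 12-week library on cuprizone (adjusted p = 0.0836), and trophic factors and cytokines without that library (0.0665 and 0.445) or the 4-week recovery library (0.21 and 0.813). Lysosome was lost without the 4-week library on cuprizone (0.522) or the 12-week recovery library (0.507), and immediate early genes without the 4-week library on cuprizone (0.816) or the 4-week recovery library (0.0668). Astrocyte markers had a median of 0.42 (7 of 7 higher, camera adjusted p = 0.00039, adjusted p = 0.213 with an estimated correlation), which became 0.15 (adjusted p = 0.21) without the 4-week recovery library. Neutrophil (0.40, adjusted p = 0.168) and monocyte genes (-0.34, adjusted p = 0.111) passed camera only with the duration block, at adjusted p = 0.0021 and 0.023, and had 0.399 and 0.306 with an estimated correlation.

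In Trem2-/- microglia no gene passed between cuprizone and recovery (limma, 64 at an unadjusted p under 0.05, 0 called and 312 with the duration block). Clec7a measured 0.96 ± 0.31, Apoe 0.88 ± 0.24 and Nudt21 -1.55 ± 0.56. The disease-associated list rose slightly (21 of 28 higher, median 0.19, 0 called, 0 adjusted over the list alone, camera adjusted p = 3.2e-08, adjusted p = 0.867 with an estimated correlation), and its adjusted p was 0.249 without the 12-week Trem2-/- library on cuprizone. Interferon response (0.22, adjusted p = 0.011) and cytokine genes (0.17, adjusted p = 0.033) passed camera with 0 called and an adjusted p of 0.867 with an estimated correlation. These calls were lost without the 12-week recovery library (adjusted p = 0.26 and 0.681), and without the 12-week library on cuprizone for interferon response (0.828) or the 4-week one for cytokines (0.728).

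The change from cuprizone to recovery differed between the genotypes for the disease-associated list (28 of 28 positive, median 1.04, 0 called, 14 adjusted over the list alone, camera adjusted p = 7.7e-32, adjusted p = 0.226 with an estimated correlation) and for interferon response (20 of 23 positive, 0.69, adjusted p = 1e-08, adjusted p = 0.226 with an estimated correlation). No single gene passed (limma, 161 at an unadjusted p under 0.05, 0 called and 555 with the duration block). Values were 3.07 ± 0.60 for Cst7, 2.97 ± 0.55 for Apoc1, 2.26 ± 0.44 for Clec7a and 2.09 ± 0.35 for Gpnmb. Trophic factors (0.20, adjusted p = 0.00029), cholesterol efflux and lipid handling (0.22, adjusted p = 5e-07), cytokines and chemokines (0.40, adjusted p = 0.00014), proliferation (0.22, adjusted p = 0.0055), MHC class II (0.32, adjusted p = 0.0075), lysosome (0.11, adjusted p = 0.047) and homeostatic genes (-0.19, adjusted p = 0.0063) passed too. Their adjusted p-values were 0.226, 0.287, 0.241, 0.241, 0.226, 0.674 and 0.674 with an estimated correlation. Without the 4-week WT recovery library the trophic (adjusted p = 0.0574), cytokine (0.142), proliferation (0.0711) and homeostatic (0.511) calls were lost. MHC class II was lost without the 12-week WT (0.0992) or 12-week Trem2-/- library on cuprizone (0.0517) or the 4-week Trem2-/- recovery library (0.0716). Proliferation was also lost without the 12-week Trem2-/- recovery library (0.264), and the homeostatic call without the 12-week WT (0.178) or 4-week Trem2-/- library on cuprizone (0.349) or the 12-week Trem2-/- recovery library (0.545). The lysosome call was lost without the 4-week WT (0.398) or 12-week Trem2-/- library on cuprizone (0.517), the 12-week WT (0.319) or the 4-week Trem2-/- recovery library (0.73). Neutrophil (-0.59, adjusted p = 0.164) and astrocyte genes (-0.36, adjusted p = 0.0705) passed camera only with the block, at adjusted p = 0.00073 and 0.028, and had 0.349 and 0.304 with an estimated correlation.

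Recovered WT microglia still lay above the control at disease-associated genes as a group. The list had 26 of 28 members higher and a median of 0.73, with 0 called and 12 adjusted over the list alone (camera adjusted p = 2.3e-23, adjusted p = 0.179 with an estimated correlation). Gpnmb measured 2.91 ± 0.30 (adjusted p = 0.1), Apoc1 3.42 ± 0.48 (adjusted p = 0.35) and Apoe 2.03 ± 0.29 (adjusted p = 0.35). None of the genes passed singly, with 242 at an unadjusted p under 0.05 in limma, while the duration block gave 18 higher and 1 lower. The block called Gpnmb (3.06, adjusted p = 0.0015), Apoc1 and Apoe (0.042 each), Axl and Gpr65 (0.045 each) and, as the 1 lower gene, the mitochondrial transcription factor Tfb2m (-1.37, adjusted p = 0.045). A second Tfb2m probe of similar brightness (mean level 6.01 against 6.44) differed in sign for WT cuprizone minus control, at 0.19 against -0.24. The block called 1 gene with the library of conflicting labels counted as 4 weeks. Homeostatic genes stayed lower (median -0.23, 0 called, camera adjusted p = 6.9e-05, adjusted p = 0.529 with an estimated correlation, median -0.06 with the block) and cytokines and chemokines higher (0.62, 0 called, 4 adjusted over the list alone, adjusted p = 6.9e-09, adjusted p = 0.179 with an estimated correlation, 0.30 with the block). Border macrophage markers were higher too (10 of 13, median 0.37, 0 called, 1 adjusted over the list alone, adjusted p = 0.044, adjusted p = 0.673 with an estimated correlation), at 0.96 with the block and -0.17 (adjusted p = 0.91) without the 4-week recovery library. Glycolysis (0.25, adjusted p = 0.00074), cholesterol efflux and lipid handling (0.21, adjusted p = 6.9e-05), trophic factors (0.34, adjusted p = 0.0017), interferon response (0.37, adjusted p = 0.006) and phagocytic receptors (0.02, or 0.14 with the block, adjusted p = 0.044) passed. Their adjusted p-values were 0.179, 0.432, 0.329, 0.432 and 0.537 with an estimated correlation. The interferon call was lost without the 12-week recovery library (adjusted p = 0.137) and the phagocytic one without the 4-week recovery library (0.462) or either Trem2-/- library on cuprizone (0.0635). Lysosome genes (0.04, adjusted p = 0.369) passed camera only with the block (0.11, adjusted p = 0.01, adjusted p = 0.244 with an estimated correlation).

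Recovered Trem2-/- microglia had higher values than their control at chemokine genes and Apoe, again without a gene past the threshold. That single control lay below the WT control at Ccl8 (-1.23), Ifi207 (-0.87), Ccl7 (-0.63) and Apoe (-0.26) and in its border macrophage median (6.19 against 6.76). How much of the values below stems from that 1 array cannot be told. Ccl8 measured 2.38 ± 0.47, Ifi207 2.36 ± 0.28 (adjusted p = 0.27), Apoe 1.99 ± 0.29 (adjusted p = 0.42), Ccl7 1.85 ± 0.25 and Ms4a7 1.68 ± 0.30. limma called 0 genes, with 151 at an unadjusted p under 0.05. With the block it called 18 higher and 1 lower, among them Ccl8 (0.042), Ifi207 (0.022), Apoe (0.031), Ccl7 (0.015) and Ms4a7 (0.036), each with its adjusted p, but 2 genes with the library of conflicting labels counted as 4 weeks. Disease-associated genes had a median of 0.32 (22 of 28 higher, 0 called, 5 adjusted over the list alone, camera adjusted p = 5.9e-08, adjusted p = 0.526 with an estimated correlation). Cytokines and chemokines rose (21 of 23, median 0.66, 0 called, 5 adjusted over the list alone, camera adjusted p = 1.8e-14, adjusted p = 0.185 with an estimated correlation), at 0.41 with the block. All 13 border macrophage genes were higher, with a median of 1.10 and 1.63 with the block (camera adjusted p = 2.8e-07, adjusted p = 0.551 with an estimated correlation), and the adjusted p was 0.0564 without the 4-week recovery library. Neutrophil genes had a median of -1.86 (adjusted p = 0.0054, adjusted p = 0.853 with an estimated correlation), which was -0.44 (adjusted p = 0.425) without the 12-week library and -0.05 with the block (adjusted p = 0.254). Cholesterol efflux and lipid handling genes (0.10, adjusted p = 0.056) passed camera only with the block (0.19, 2 called, adjusted p = 0.00051, adjusted p = 0.373 with an estimated correlation). Astrocyte genes passed only without it (-0.45, adjusted p = 0.028, adjusted p = 0.551 with an estimated correlation, against -0.42, adjusted p = 0.0867) and not without the 12-week recovery library (adjusted p = 0.308). Interferon response (0.38, adjusted p = 0.00063), trophic factors (0.22, adjusted p = 0.0011), phagocytic receptors (0.08, or 0.21 with the block, adjusted p = 0.027) and neuron markers (-0.70, 4 of 4 lower than in that same control, adjusted p = 0.0031) passed with 0 called, and had 0.526, 0.385, 0.853 and 0.334 as adjusted p with an estimated correlation. Without the 4-week recovery library the phagocytic (adjusted p = 0.684) and neuron (0.0699) calls were lost.

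Matched by diet over all 5 conditions, the genotypes differed at 28 genes, 8 higher and 20 lower in Trem2-/- cells. The lowest was G530011O06Rik (-5.19 ± 0.41, adjusted p = 0.00038), a Riken gene outside the naming rule, chosen after its values were seen. Below Trem2 in size among the genes that the rule names were Mid1 (-2.86 ± 0.21, adjusted p = 0.00031), the olfactory receptor gene Olfr111 (-2.71 ± 0.17, adjusted p = 8.6e-05), Lpl (-2.65 ± 0.41, adjusted p = 0.036), Itgax (-2.19 ± 0.36, adjusted p = 0.0498) and Lrmda (-2.18 ± 0.21, adjusted p = 0.0024). Slamf7 (-1.66 ± 0.24), St8sia6 (-1.49 ± 0.18), Cd300lb (-0.98 ± 0.15), Olfr110 (-0.88 ± 0.14), Entpd4 (-0.77 ± 0.10), the nonclassical MHC gene H2-M3 (-0.76 ± 0.11) and Tbc1d8 (-0.60 ± 0.10) were lower too. Rises were measured for Rasgrf2 (3.16 ± 0.13, adjusted p = 1.5e-06), Apobec2 (1.05 ± 0.13, adjusted p = 0.012), the detoxifying enzyme Glo1 (1.0 ± 0.13, adjusted p = 0.021), the mitochondrial transhydrogenase Nnt (0.87 ± 0.14, adjusted p = 0.036), H2-T24 (0.82 ± 0.12), Ache (0.76 ± 0.10) and Pecam1 (0.63 ± 0.09). Trem2, Olfr111, Olfr110, H2-M3, H2-T24, Glo1 and Apobec2 lie on the same chromosome in the assembly GRCm38.p6. limma found 1162 genes at an unadjusted p under 0.05.

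The count of 28 moved with the libraries used. It was 8 without any 1 of the 4 libraries on cuprizone, 13 without any 1 of the 4 recovery libraries and 103 without either control library, since a left-out library unpairs its condition. It was 6 in the control and 4-week libraries alone and 60 in the 12-week libraries alone. Rasgrf2, Trem2, Mid1, Olfr111 and Lrmda kept their calls in all 10 fits with a library left out. Lpl and Itgax kept theirs in 2 of 10. Disease-associated genes were lower as a group (28 of 28, median -1.13, 2 called, 21 adjusted over the list alone, camera adjusted p = 8.2e-21, adjusted p = 0.357 with an estimated correlation), as were cytokines and chemokines (-0.24, 0 called, 9 adjusted over the list alone, adjusted p = 5e-06), MHC class II (-0.25, 0 called, 5 adjusted over the list alone, adjusted p = 0.00029) and glycolysis (-0.24, 0 called, 5 adjusted over the list alone, adjusted p = 0.00056), each at an adjusted p of 0.357 with an estimated correlation. Homeostatic genes were higher (27 of 29, median 0.13, camera adjusted p = 4.5e-05, adjusted p = 0.432 with an estimated correlation). Neutrophil markers were lower too (-0.37, adjusted p = 0.023, adjusted p = 0.497 with an estimated correlation), but without either 4-week recovery library the median was -0.11 (adjusted p = 0.758). Monocyte markers (-0.37, 7 of 10 lower, 0 called, 2 adjusted over the list alone, adjusted p = 0.0449) were lower and neuron markers (0.20, 4 of 4 higher, 0 called, adjusted p = 0.0394) higher, each at an adjusted p of 0.357 with an estimated correlation. The monocyte call was lost without either control (adjusted p = 0.0634), either 4-week library on cuprizone (0.131) or either 4-week recovery library (0.189), and the neuron call without either control (0.339) or either 4-week library on cuprizone (0.0887). Lysosome (-0.11, adjusted p = 0.0027), cholesterol efflux and lipid handling (-0.15, adjusted p = 0.0003), interferon response (-0.16, adjusted p = 0.0027), the Trem locus (-0.46, adjusted p = 0.007), trophic factors (-0.20, adjusted p = 0.0155), cholesterol synthesis (-0.05, adjusted p = 0.0394) and MHC class I genes (-0.03, adjusted p = 0.0394) were lower as well. With an estimated correlation the adjusted p was 0.446 for interferon response, 0.362 for lysosome and 0.357 for the others. Without a library on cuprizone, whichever of the 4, the interferon, synthesis and MHC class I calls were lost (adjusted p up to 0.153, 0.127 and 0.121), the last 2 also without either 4-week recovery library (0.0639 and 0.0767).

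Between the control libraries, which have no replicates and no test, 24 genes differed by over 2-fold, 8 higher and 16 lower in the Trem2-/- library. Among genes with an assigned symbol and a mean over the 10 arrays above the table's median, the largest rises were Rasgrf2 (2.98), the replication helicase subunit Mcm7 (1.26), Plp2 (1.14), Ly6k (1.10), Fabp7 (1.09) and H2-T24 (1.02). The lowest of these genes were Trem2 (-3.19), Olfr111 (-2.81), Mid1 (-2.25), the histone gene H3c4 (-1.80), Slc15a2 (-1.71), Tfb2m (-1.55) and Ccl8 (-1.23). Over all libraries a second Tfb2m probe differed between the genotypes by 0.02, against -0.62 for the probe used. The Riken gene G530011O06Rik, outside the rule, differed by -3.07. As a description of these libraries, the medians of disease-associated (-0.13), MHC class II (-0.22), cytokine (-0.19) and border macrophage genes (-0.45) lay at percentile 0 of random lists and those of proliferation (0.22) and neuron genes (0.57) at 99.7 and 100. Homeostatic genes (-0.06) lay at percentile 7.

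Libraries titled 12 weeks differed from those titled 4 weeks at 2194 genes, 887 higher and 1307 lower, and 3954 at an unadjusted p under 0.05 (limma, 8 arrays with the group as a block). Feeding time and run of sample numbers coincide here and cannot be told apart. Quantile normalization gave 1088 higher and 1063 lower. Neutrophil genes were lower: S100a8 differed by -6.63 ± 0.59 (adjusted p = 0.00027) and S100a9 by -6.44 ± 0.39 (adjusted p = 5.8e-05). The siderophore binder Lcn2 differed by -4.12 ± 0.44 and the granule proteins Ngp and Camp by -4.04 ± 0.33 and -3.37 ± 0.36. Interferon beta (Ifnb1) rose by 4.81 ± 0.26 (adjusted p = 3.9e-05), at 8.49 to 10.43 in the 12-week libraries against 4.04 to 4.61 in the control and 4-week libraries. These low levels of Ifnb1, and those of Lcn2 (3.47 to 4.31) and Ngp (3.73 to 4.80) in the 12-week libraries, lay below the table's median of 5.27, near background, which leaves the size of their differences uncertain. S100a8 and S100a9 had levels below it in part of the 12-week libraries. The interferon-inducible chemokine Cxcl10 rose by 2.07 ± 0.14, the oxidant-response gene Srxn1 by 2.02 ± 0.13, the growth factor Hbegf by 1.92 ± 0.18 and endothelin (Edn1) by 1.89 ± 0.19. The noncoding RNA Rmrp differed by -2.19 ± 0.15.

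By group, all 10 neutrophil genes passed as lower (median -3.62, camera adjusted p = 3.9e-10), as did 9 of 10 monocyte genes (-1.42, adjusted p = 2.1e-06) and 11 of 13 border macrophage genes (-1.12, adjusted p = 3.9e-10), with Cd163 at -1.65 ± 0.16 and Lyve1 at -1.42 among them. The same numbers passed when adjusted over the list alone. Homeostatic genes were lower as well (27 of 29, median -0.23, 12 called, 13 adjusted over the list alone, adjusted p = 0.00071, adjusted p = 0.453 with an estimated correlation), with the transcription factor Sall1 at -0.72 ± 0.11. Cytokines and chemokines rose (median 0.32, 11 up and 1 down, 11 and 2 adjusted over the list alone, adjusted p = 0.0018), with Tnfsf9 at 1.60 ± 0.24 and Il12b at 1.52 ± 0.17. With an estimated correlation the adjusted p was 0.329 for the neutrophil, monocyte, border macrophage and cytokine lists. The disease-associated list did not pass (-0.22, 0 up and 3 down, adjusted p = 0.144), and neither did interferon response (-0.22, 3 up and 3 down, adjusted p = 0.828), whose members split between Ifit1 at 1.39 ± 0.19 and Xaf1 at -1.43 ± 0.15. Phagocytic receptors fell (-0.26, 2 up and 8 down, 2 and 9 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.329 with an estimated correlation), among them Lrp1 at -0.99 ± 0.13 and Clec4n at -0.98. Lysosome (-0.24, 2 up and 6 down) and cholesterol efflux genes (-0.26, 2 up and 5 down) passed at adjusted p = 0.0447 each, with 0.4 and 0.542 with an estimated correlation. Any 1 library left out ended the lysosome call (adjusted p up to 0.0807), and any but a WT recovery library ended the efflux call (up to 0.102). The count of genes was 186 with the library of conflicting labels at 4 weeks. Leaving out a library gave 1064 without either Trem2-/- recovery library and 1229 without either WT library on cuprizone.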

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

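The tests weighed here were chosen only after the result was seen. Gpnmb was picked out by the test of the difference between the genotypes: its response to cuprizone differed by -4.57 ± 0.43 (adjusted p = 0.045) between Trem2-/- and WT microglia. The control levels of 3.82 and 4.64 lay below the table's median of 5.27, near background, as did the Trem2-/- levels of 4.57 and 4.52 on cuprizone, so the size is uncertain, also for the direct difference of -3.76 ± 0.25 on cuprizone. Probes naming no gene or several lie outside the gene table, and 2 of the 1652 such probes tested passed the threshold for Trem2-/- against WT on cuprizone, with 13358 probes tested in all. Probe 10523717, which names no gene, differed by -4.97 ± 0.53 (adjusted p = 0.0147), with levels of 9.99 and 9.41 in the WT libraries on cuprizone, 4.96 in the WT control and 4.73 in both Trem2-/- libraries on cuprizone. The low levels again lay near background, which leaves the size of the difference uncertain. Probe 10560608, which names several genes, differed by -2.05 ± 0.25 (adjusted p = 0.0302).

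Disease-associated genes, Gpnmb among them, were lower in Trem2-/- than in WT microglia on cuprizone, with a list median of -1.90. Under the other scalings of the deposited columns, the median nearest to 0 was -1.83. The columns were already close to a common scale, so these scalings could change little. They cannot decide whether scaling before deposit played a part. A smaller share of microglia among the sorted Trem2-/- cells is argued against by the homeostatic list, whose lower quartile was 0.19, above 0. A wrong label on the Trem2-/- library with conflicting feeding times is argued against as the whole cause by the pair of 4-week libraries, which do not include it and gave -1.66. A response that needs Trem2 stays a hypothesis consistent with these values, found and tested on the same libraries, and other differences between the mouse lines were not tested.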

How the results depend on the processing

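The duration block with the conflicting library counted as 4 weeks, the covariate and the 2 subsets of libraries for the genotype comparison were chosen after seeing the data, and the remaining alternatives were fixed before. The labels give no replicate numbers to pair by, and libraries were matched by diet or by group only in the models over 5 diet conditions and of 12 against 4 weeks. Among called named genes, 1736 values kept their direction and side of the threshold, 521 no longer passed and 1 changed sign. For called lists 1758 were kept, 269 no longer passed and 20 changed sign. For values past no threshold, 257 of single genes and 172 of lists passed under some alternative. Dim genes were limited by background, with a filter at a log2 intensity of 5.27.

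Titled duration as a block gave 105 genes for WT cuprizone against control, 13 for Trem2-/- cuprizone against control, 9 for the genotype difference in that response, 153 for Trem2-/- against WT on cuprizone, 10 for the genotypes in recovery, 7 for WT recovery against cuprizone, and 19 for recovery against control in either genotype. With the conflicting library counted as 4 weeks the block gave 37 for WT and 0 for Trem2-/- cuprizone against control, 1 for the difference between these, 0 for WT recovery against cuprizone, 55 and 8 for the genotypes on cuprizone and in recovery, and 1 and 2 for WT and Trem2-/- recovery against control. The neutrophil list mean as a covariate gave 110 for WT and 5 for Trem2-/- cuprizone against control, 8 for the difference between these, 150 and 18 for the genotypes on cuprizone and in recovery, 7 for WT recovery against cuprizone, 2 for the genotype difference in that change, and 14 for recovery against control in either genotype. Subtracting array medians gave 0 for the genotype difference in the response to cuprizone. For all of these the cause was not tested.

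Over the 5 diet conditions, the 28 genes became 44 with no filter on dim genes, 62 with a variance trend and robust shrinkage, 6 with no diet block, 8 with phase as the block, 8 with the conflicting library counted as 4 weeks, 6 in the control and 4-week libraries alone and 60 in the 12-week libraries alone. The 12 against 4 weeks count became 186 with that library counted as 4 weeks. Beyond the smaller number of libraries in the subsets, the cause was not tested.

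Leaving out each library in turn gave 2 to 16 genes for WT cuprizone against control, 0 to 1 for the genotype difference in that response, 0 to 42 and 0 to 4 for the genotypes on cuprizone and in recovery, 8 to 103 over the 5 diet conditions and 1064 to 1621 for 12 against 4 weeks. A group left with 1 library was assumed to vary like the other groups. These list medians changed sign, and the cause was not tested: border macrophage ran from -0.0738 to 1.18 for WT cuprizone and from -0.17 to 0.98 for WT recovery, each against control. In recovery between the genotypes, the Trem locus ran from -0.59 to 0.0896 and cholesterol efflux and lipid handling from -0.31 to 0.0353. In WT recovery against cuprizone, homeostatic genes ran from -0.01 to 0.27 and lysosome genes from -0.20 to 0.0057. In Trem2-/- recovery against cuprizone, interferon response ran from -0.0513 to 0.38 and cytokines and chemokines from -0.0063 to 0.33. Homeostatic genes ran from -0.30 to 0.0126 for the genotype difference in that change, and phagocytic receptors from -0.12 to 0.15 and from -0.0835 to 0.22 for WT and Trem2-/- recovery against control.

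Under other settings these values changed sign, and the cause was not tested. The neutrophil median was 0.0148 for Trem2-/- cuprizone against control with the block, 0.0010 for the WT with the conflicting library moved, and 0.16 between the genotypes in the 12-week libraries alone. Cytokines and chemokines stood at -0.0245 in Trem2-/- recovery against cuprizone with that library moved. With no filter on dim genes the Trem locus stood at 0.0885 and trophic factors at 0.0011 between the genotypes over the 5 diet conditions. Nlrc5 stood at -0.12 for 12 against 4 weeks with the mean over its probes, against 0.37 for its brightest probe.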

Other observations

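Among the tests weighed below, only the 2 counts of other splits were chosen before the results were seen. Border macrophage genes followed the feeding time as titled in both genotypes. Between 4 and 12 weeks, feeding time coincides with the run of sample numbers and cannot be told apart from it. The controls belong to the same run as the 4-week libraries. The mannose receptor Mrc1 had log2 levels of 9.49 to 9.64 in the 4-week libraries with and without recovery, 8.30 and 8.03 in the controls and 8.29 to 8.67 in the libraries titled 12 weeks. The haptoglobin-hemoglobin receptor Cd163 had 7.10 to 7.41 in the 4-week libraries, 5.77 and 5.31 in the controls and 5.26 to 5.98 in those titled 12 weeks. The list median followed the same order, at 7.69 to 8.18, at 6.76 and 6.19, and at 6.78 to 6.96.

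Neutrophil genes were lower in the 12-week libraries, with S100a8 at 10.86 to 12.30 in the control and 4-week libraries and at 3.01 to 6.59 in those titled 12 weeks. The labels do not give the markers of the sort, so whether it removed whole neutrophils cannot be stated. Of the 10 list genes, 0 belong to another list. Neutrophil RNA in varying amounts among the sorted cells is a possible explanation: 10 of the 10 members were highest in the WT library of 4 weeks with recovery among the control and 4-week libraries. A difference between the runs of sample numbers stays open and cannot be told apart from feeding time, because 0 libraries of the second run were titled control or 4 weeks. The library with conflicting labels had a neutrophil median of 5.11, near the others of its run and below the 7.76 of the 4-week Trem2-/- library.

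Genes differing between the genotypes in all 5 diet conditions were frequent on the chromosome that carries Trem2: 6 of 27 called genes other than Trem2 (22.2%) lay on it, against 543 of the genes not called, with 10221 elsewhere (5.04%), an odds ratio of 5.4 (one-sided Fisher's exact p = 0.002, genes taken as independent). Counted in tested genes from Trem2, Apobec2 was number 4, Olfr111 60, Olfr110 61, H2-M3 63, H2-T24 75 and Glo1 205, which is consistent with DNA of another mouse strain around Trem2 in the Trem2-/- mice. For these genes the difference in the control libraries was 1.02 times the mean over the conditions (median), and 0.42 times for Glo1. The test calls genes whose difference varies little over the conditions, control included, which favours a ratio near 1. The ratio therefore cannot decide whether their response to cuprizone differs between genotypes. For called genes on other chromosomes the ratio was 0.57 and left this open. Nnt, which carries a deletion in the substrain C57BL/6J, was higher in Trem2-/- cells at 7.50 to 7.76 against 6.39 to 7.27, and the substrain of either line was not given. Its difference was 0.23 in the control libraries against 0.87 over the 5 conditions, a ratio of 0.26. The call of Nnt held in 2 of 10 fits with a library left out, and a difference in substrain was not tested.

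Other splits of the libraries were counted for the larger comparisons. For Trem2-/- against WT over 5 diet conditions, 3 of 100 splits drawn from 126 called at least the real 28 genes, the real one included, and the highest other called 169. The 2 other splits kept the control pair and the 4-week recovery pair each on 1 side and parted the remaining pairs by genotype. With diet as a block, a pair kept on 1 side adds nothing to the estimated difference. Both splits thus estimate the genotype difference in the remaining pairs, and do not show what a grouping unrelated to genotype would give. The fit matches libraries by diet, and of the 16 splits that part every pair of the same diet the highest other called 0, and these are too few for a share under 0.05 (smallest 0.0625). For 12 against 4 weeks, 1 of the 32 splits that could be fitted, the real one, called as many as 2194, and the highest other called 1. The fit matches libraries by group, and of the 8 splits that part every pair of the same group the highest other called 0, and these are again too few for a share under 0.05 (smallest 0.125).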
